A study of Mus musculus with 6 samples.

How the data were processed

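RNA from the quadriceps femoris of C57BL/6 mice was measured on an Illumina mouse BeadArray, a chip on which each transcript is read by beads carrying a probe. Per the labels, 3 arrays carried RNA of wild-type mice and 3 carried RNA of mice with a transgene for a truncated human RORalpha1 under the human skeletal alpha-actin promoter, and the mice were fasted overnight and killed in the morning. The 6 arrays lay on 1 chip, wild type at the first positions and transgenic at the last, so position on the chip and genotype cannot be told apart, and there was no second chip to use as a batch.

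The deposited signal table holds bead-averaged intensities on a linear scale, written with BeadStudio 2.3.41 per the submitters' processing notes, with no value at or below 0. Beside each signal the deposited table gives a detection p-value per the file headers, but these values rise with signal and were therefore read as 1 minus the p-value. The background setting used to export the intensities is not given in the sources used here. The authors' second table holds log2 values, which equal the log2 signal minus a constant per array and minus each probe's median over the 6 arrays. Its scale, centring and direction were found by setting it against the signals. Its array medians lay between -0.023 and 0.014.

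In the deposited signal table the signal columns were displaced against the probe identifiers and the detection values by 0 to 21 rows, most often by 17 (39418 probes). As deposited, signal and detection values were almost unrelated (Spearman's rho across probes 0.026 to 0.034), and Acta1, the most abundant actin transcript of skeletal muscle, stood at 176.8 on wild-type array 1. Signals were therefore returned to their probes by matching differences between arrays to the log2 table within 0.002. This placed 46611 of 46632 probes, with a largest remaining difference of 2.2e-06. The 21 signal rows matched to no probe and the 21 probes left without a signal were not used. Detection values, which took no part in the matching, then followed the signals on every array (rho at least 0.99999), and Acta1 stood at 51790.2 on wild-type array 1.

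Probe names came from a platform annotation table: 29976 probes had 1 gene symbol, 10 had several and 16646 had none here. Symbols were checked by Entrez identifier against a RefSeq table of assembly GRCm38.p6, which held 29921 of the probes with 1 symbol and changed 0 of them. No coordinates are printed, because the files name no genome build. Where a gene had several kept probes, the probe with the highest mean was used for lists and named genes. For lists with the deposited log2 values, which are centred per probe, this was the highest centred mean, which need not be the brightest probe.

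Intensities were background corrected by normexp with negative-control values inferred from the detection values, offset by 16, quantile normalised and put on the log2 scale (neqc of limma 3.58.1 in R 4.3.3; alignment in Python 3.11.15). Probes detected at p under 0.05 on at least 3 of the 6 arrays were kept (14420). Of the kept probes, 11335 had a gene symbol. Precision is limited by the number of arrays.

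Before averaging, arrays were compared over the 5236 probes detected on all 6 arrays with a mean above 9. For 525 genes with several such probes, the difference between 2 arrays was correlated between 2 probes of the same gene. A real difference in RNA moves both probes, and bead noise does not. Arrays of one group with r under 0.1 were counted as 1 sample, and their normalised log2 values were averaged. This left 2 samples per group. The design written before the data were examined took the 6 arrays as separate samples, and its counts are given beside those of the averaged samples. The averaging departs from that design. It was decided after the counts of changed probes from both fits had been seen, and the comparison of probes of the same gene was made after that.

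Groups were compared with limma (lmFit and eBayes, two-sided, Benjamini-Hochberg adjustment over kept probes, threshold 0.05). An exact permutation test of 2 samples against 2 cannot give a p below 0.333, and of 3 arrays against 3 none below 0.1. All adjusted p-values below come from limma. The labels do not say which arrays came from separate mice, so p-values measure the spread between these samples, which may in part be technical. In 26 gene lists fixed before the data were examined, camera of limma compared each list with the other genes at a preset correlation of 0.01. camera with an estimated correlation and fry were alternatives. Members past the threshold are counted over all probes and again adjusted over the list alone.

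Named genes followed a rule also fixed before the data were examined: Rora and Acta1; the 12 largest rises and 12 largest falls with adjusted p under 0.05 and no overlap of 3 against 3 arrays in the fit to 6 arrays; up to 4 members of each list with the smallest p; and a set of metabolic, clock and signalling genes. The smallest p of a list was taken from the averaged samples, which departs from the fixed design. Some genes outside the rule are described too, among them Adipoq, Trim63, Myl3 and Thrsp, and were not chosen beforehand. Some genes picked by the rule, such as Mt1, are not described. A gene detected on no array of a group has only a bound there. Its fold is then "at least" the brighter group's mean over the dimmer group's mean of, per array, the higher of the lowest detected signal and its own.

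The procedure was tested on simulated data for the comparison of 2 samples against 2 over 14420 probes, with spreads drawn from the fitted prior. In it 200 probes were changed at once. Of planted log2 changes of 4, 98.5% were recovered, of changes of 2, 89.6%, and of changes of 1, 5.97%. There were 12 false calls among 14220 unchanged probes. With so many planted changes the adjustment is more lenient than in the data, where 1 probe passed. The shares therefore do not give the power of the comparison made here. A first version of the simulation drew spreads from the fitted values of each probe and gave more false calls, and it was revised once after that was seen. The oxidative phosphorylation list, planted with a shift, was found, with no other of the 26 lists called. That run was set to stop if the list was missed or if more than 2 lists passed. Its noise was independent between probes, so it cannot show how often camera calls a list whose genes vary together. Alternatives to the background correction, normalisation, filter, variance model, weights, threshold, probes per gene and list test were run, as were the deposited log2 values, the replicate number as a block and the omission of each array, for which the probes kept with all 6 arrays were retained after a filter remade without the array was seen to remove Ucp1. Taking the 6 arrays separately was run too, with and without the RNA sample as a random block. Before the probe filter, the 21 unmatched signal rows were the only per-array values left out.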

Results

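Gene expression in the quadriceps femoris, a thigh muscle, was measured on 6 arrays, 3 labelled wild type and 3 labelled as carrying the RORalpha1delDE transgene. RORalpha is a nuclear receptor, and the transgene encodes a human RORalpha1 that lacks its E region and part of the hinge, expressed from a skeletal muscle promoter. All mice were kept on a 12 h light cycle and a diet with 4.6% fat. Between 13979 and 14887 probes were detected per array, and the median signal ran from 154.5 to 174.9. The comparison asks which muscle transcripts differ between transgenic and wild-type mice.

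Arrays 1 and 2 of each group showed no difference shared by bright probes of the same gene and were counted as 1 sample. Bead noise itself was not measured. Wild-type arrays 1 and 2 differed by more than 2-fold at 0 of 5236 bright probes, and differences between them at 2 probes of the same gene were unrelated (r = 0.0279 across 525 genes). Transgenic arrays 1 and 2 gave 0 probes and r = 0.0159. Replicate 3 differed from the other arrays of its group at 55 to 101 of these probes, with r from 0.687 to 0.749. Genes are not independent replicates, so r is only descriptive. With these arrays averaged, n = 2 against 2. Means ± SD below are over these samples, on the log2 scale.

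**Figure D1:**
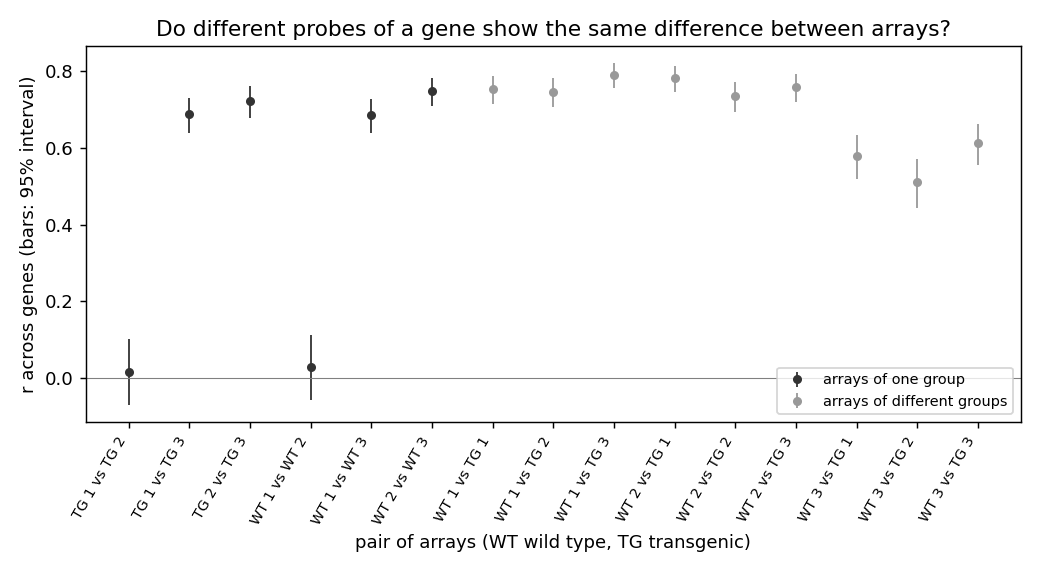
Each point is the correlation, across 525 genes, of the difference between 2 arrays at 2 probes of the same gene, with its 95% interval, for every pair of the 6 arrays. Arrays 1 and 2 of each group lie at 0.0279 and 0.0159, and all other pairs lie between 0.511 and 0.791.

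Ucp1, the uncoupling protein of brown fat, was at 12.45 ± 0.38 in wild-type muscle (SD, n = 2) and was detected on none of the 3 transgenic arrays. With the background correction used here it was at least 97.7-fold lower in the transgenic samples (adjusted p = 0.00103). The size depends on the processing: over the alternatives its log2 difference ran from -7.39 to -5.18, the smallest with the deposited log2 values. The next largest differences among named genes were in genes of fat cells and of fatty acid synthesis. Cidea, a lipid droplet protein of brown adipocytes, was at 11.34 ± 0.70 in wild type and 7.30 ± 0.04 in transgenic samples, and Fasn, fatty acid synthase, at 12.26 ± 0.21 and 8.94 ± 0.84 (SD, n = 2 each). Neither passed the threshold with the processing used here (adjusted p = 0.0833 and 0.152). Both calls depend on it: Cidea passed with offset 50, without background correction, with median centring, with the deposited log2 values and with an intensity trend (adjusted p from 0.00477 to 0.0426), and Fasn under the same settings except median centring (adjusted p from 0.0249 to 0.0475).

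Of 14420 probes, 0 were higher and 1, that of Ucp1, was lower in the transgenic samples at an adjusted p under 0.05, while 1102 had an unadjusted p under 0.05 against 721 expected by chance. Median centring in place of quantile normalisation gave 1 higher and 2 lower. Without transgenic replicate 3, 1 was higher and 8 were lower, the named ones being Apoc1, Cidea, Cidec, Cyp2e1, Fasn, Scd1, Tmem45b and Ucp1. When the 6 arrays were taken as separate samples, limma called 54 probes, 20 higher and 34 lower, 46 of them on named genes. These 54 calls treat arrays 1 and 2 of a group as separate mice. The count was 418 without wild-type replicate 3 and 11 to 16 without any 1 of the arrays numbered 1 and 2. With the samples averaged, 48 probes were at least 2-fold higher and 118 at least 2-fold lower without overlap of the samples. Absence of overlap alone has a chance share of 33.3% with 2 against 2.

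Among the 12 largest falls with 6 arrays, also by each gene's brightest probe, apart from Ucp1, Cidea and Fasn, Elovl6, an enzyme that lengthens fatty acids, differed by -2.79 ± 0.28 (log2, SE, adjusted p = 0.128) and was detected on 1 of the 3 transgenic arrays. Scd1, the stearoyl-CoA desaturase that makes monounsaturated fatty acids, differed by -2.26 ± 0.40 (adjusted p = 0.415). Pygl, the liver form of glycogen phosphorylase, was detected on 1 of the 3 transgenic arrays, so its difference of -1.89 is set against a level mostly not above background. Hp, which encodes the haemoglobin-binding protein haptoglobin, differed by -2.36. Depp1 differed by -2.38, from 13.96 ± 0.98 in wild type. Tmem45b, Myo1e and Nbdy differed by -2.39, -1.83 and -1.88, with Tmem45b detected on 2 of the 3 transgenic arrays. With the samples averaged, Nbdy and Tmem45b passed with offset 50, without background correction, with the deposited log2 values and with an intensity trend, and Elovl6 with the trend alone (adjusted p = 0.0295). Fgfbp1, detected on none of the transgenic arrays, was at least 2.54-fold lower, with an adjusted p of 0.178. With the 6 arrays taken separately, the 12 falls had adjusted p-values between 6.65e-06 and 0.0402.

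The 12 rises named here are the largest with 6 arrays when each gene is represented by its brightest probe. Rom1, a membrane protein of photoreceptors, was at 7.02 ± 0.37 in wild type and 9.17 ± 0.18 in transgenic samples, a difference of 2.16 ± 0.24 (adjusted p = 0.152). Zranb3, a DNA translocase of replication fork repair, was at 9.72 ± 0.15 and 11.30 ± 0.06, and Slc22a4, a carrier of organic cations, at 5.60 ± 0.00 and 7.40 ± 0.30. The 3 wild-type arrays read 5.93, 5.28 and 5.60 for Slc22a4, a spread that averaging the first 2 hides. Slc22a4 was detected on 1 of the 3 wild-type arrays and Katnal2 on 2, so their wild-type levels lie at or near background. Katnal2 was higher by 1.74, the decoy receptor gene Tnfrsf22 by 1.65 and Ush1c by 1.34. Tceal5, Plekhb1 and Gfer were higher by 1.32, 1.23 and 1.05, and Fndc10, Hmga2-ps1 and Maged2 by 1.03, 1.01 and 0.95. Dimmer probes of 3 more genes, named after their values were seen, passed with the 6 arrays taken separately: that of Il17re, detected on none of the wild-type arrays, was at least 2.85-fold higher, and those of Parp6 and Sox6 were higher by 1.05 and 1.04. The brightest probes of Il17re, Parp6 and Sox6 differed by 0.69, 0.14 and -0.46. None of the 12 passed the threshold with the samples averaged and the processing used here. Rom1 and Zranb3 did pass with offset 50, without background correction and with an intensity trend, and Zranb3 also with the deposited log2 values (adjusted p from 0.0223 to 0.0449). With the 6 arrays taken separately their adjusted p-values lay between 0.00527 and 0.0479. The probe with the largest rise of all 14420, ILMN_2457437, has no gene name here and was higher by 2.95 ± 0.24 (adjusted p = 0.0833). It passed with offset 50, without background correction, with median centring, with the deposited log2 values, with an intensity trend and without transgenic replicate 3.

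**Figure D2:**
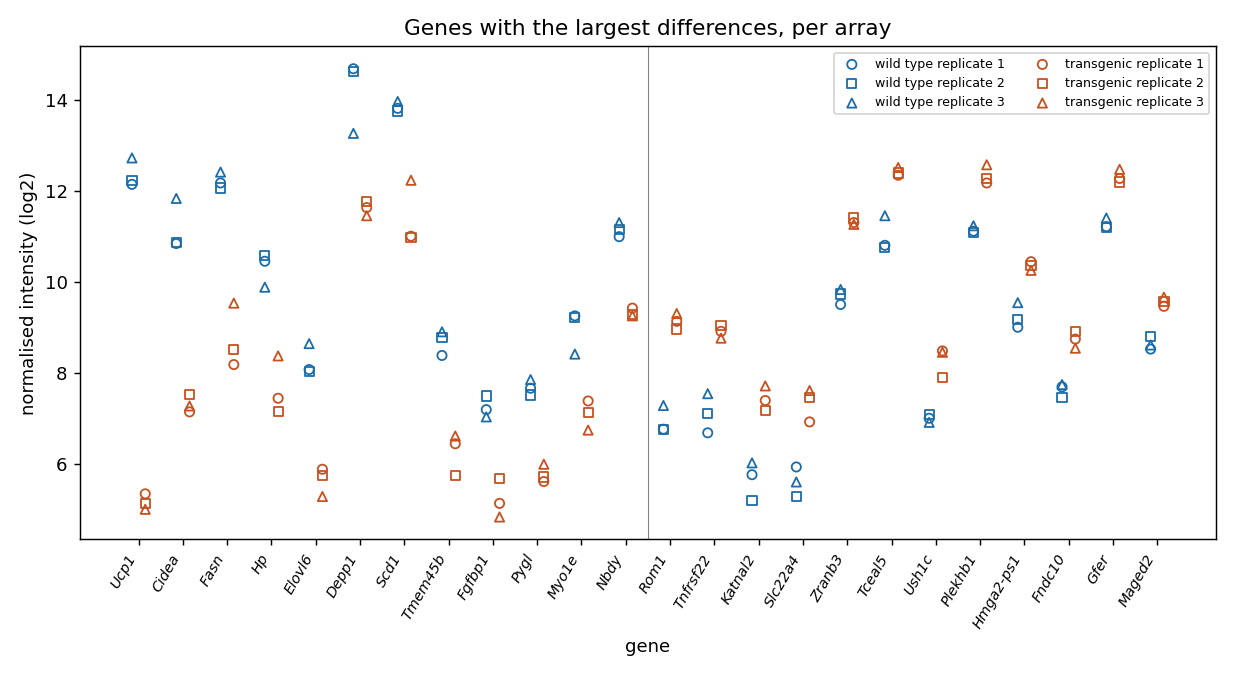
Normalised log2 intensity of the 12 largest falls (left) and 12 largest rises (right) among named genes on each of the 6 arrays, with wild type in blue and transgenic in orange. Symbols mark the replicate number, and replicates 1 and 2 of a group were counted as 1 sample. Ucp1 lay at 12.45 ± 0.38 in the wild-type samples and at 5.12 ± 0.17, below detection, in the transgenic samples (SD, n = 2).

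The lipogenesis list, genes of fatty acid synthesis and their regulators, was shifted down (camera adjusted p = 1.93e-08). The median of its 19 measured members was -0.34, with 17 below 0. With an estimated correlation its adjusted p was 0.561. Over all probes 0 members passed; adjusted over the list alone 5 fell, namely Elovl6, Fasn, Scd1, Acaca, which makes malonyl-CoA, and Thrsp. Acaca differed by -1.08 ± 0.17 and Thrsp by -1.32 ± 0.33. Scd2 differed by -0.10 ± 0.22. Srebf1 and Abca1 were detected on none of the 6 arrays. The median of the adipocyte markers in the same samples was -1.13.

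The adipocyte markers were shifted down as well (camera adjusted p = 2.58e-06, and 0.816 with an estimated correlation). Of 7 measured members, 1, Ucp1, fell over all probes, and 3, Ucp1, Cidea and Pck1, adjusted over the list alone. Pck1 was detected on none of the transgenic arrays and was at least 1.37-fold lower. The samples differed within the transgenic group. Adipoq, the adipocyte hormone adiponectin, was at 9.23 in transgenic arrays 1 and 2 and 11.05 in transgenic replicate 3, against 10.74 and 11.79 in wild type, and Cidec at 8.26 and 10.18 against 10.73 and 10.62. Ucp1 was below detection in both transgenic samples. The list's median was -2.04 without transgenic replicate 3 and -0.66 without wild-type replicate 3, past the threshold in both cases.

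The fasting, glucocorticoid and atrophy list was shifted down (camera adjusted p = 4.29e-04, and 0.971 with an estimated correlation). Its median over 19 members was -0.40, with 18 below 0, and 0 members passed over all probes or adjusted over the list alone. Cebpd, a transcription factor induced by glucocorticoids, was at 7.49 ± 0.17 in wild type and 6.48 ± 0.23 in transgenic samples, while a dimmer probe of it differed by -0.08. Angptl4, an inhibitor of lipoprotein lipase, differed by -0.84 ± 0.29. The wild-type samples stood apart from each other. Trim63, a ubiquitin ligase of muscle atrophy, was at 13.94 in wild-type arrays 1 and 2 but 11.94 in wild-type replicate 3, against 11.77 and 12.19 in the transgenic samples. Cdkn1a was at 11.62 and 8.54, against 9.18 and 7.78. The list's median was -1.05 without wild-type replicate 3, which leaves only wild-type arrays 1 and 2, and -0.23 without transgenic replicate 3. The sample made of wild-type arrays 1 and 2 was left out in no fit.

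Slow-fibre genes were shifted down with the samples averaged (camera adjusted p = 0.00375, and 0.971 with an estimated correlation), but not with the 6 arrays taken separately (adjusted p = 0.0969), with 0 of 12 members past the threshold over all probes or adjusted over the list alone. The list's median relative to wild type was -2.47 in transgenic replicate 3 and 0.34 in transgenic arrays 1 and 2. Tnni1, troponin I of slow fibres, was at 5.40 in transgenic replicate 3, against 11.01 in transgenic arrays 1 and 2 and 10.68 and 10.84 in wild type, and was detected on 2 of the 3 transgenic arrays. Myl3, a slow myosin light chain, was at 9.07 against 14.82, 14.58 and 14.34. Without that replicate the list's median was 0.34 (adjusted p = 0.0555), and without wild-type replicate 3 it was -1.17 (adjusted p = 0.108). Ankrd2, a stretch-responsive gene of slow fibres, differed by -1.22 ± 0.31 with both transgenic samples below both wild-type samples. The fast-fibre list had a median of 0.07 (adjusted p = 0.89).

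Macrophage and immune markers were shifted up with the samples averaged (camera adjusted p = 0.0304, and 0.971 with an estimated correlation), but not with the 6 arrays taken separately (adjusted p = 0.242), with a median of 0.42 over 10 members, all above 0, and 0 past the threshold either way. Adgre1, a macrophage surface marker, differed by 0.87 ± 0.31 and C1qc, a complement subunit made by macrophages, by 0.98 ± 0.37. The list's median was 0.79 above wild type in transgenic replicate 3. It was -0.02 without that replicate (adjusted p = 0.771) and 0.46 without wild-type replicate 3 (adjusted p = 0.108). Genes of fatty acid uptake and oxidation had a median of -0.11 over 24 members (adjusted p = 0.031, and 0.971 with an estimated correlation), with 0 past the threshold. With the 6 arrays taken separately this list's adjusted p was 0.117. Ppard, a nuclear receptor that drives fatty acid oxidation, differed by -0.74 ± 0.25, Acot2 by -0.52 and Cpt1b, which admits fatty acids to mitochondria, by -0.07 ± 0.19. Without transgenic replicate 3 this list's median was -0.02 (adjusted p = 0.603), and without wild-type replicate 3 it was -0.07 (adjusted p = 0.2). Probes of Etfdh, which passes electrons from fatty acid oxidation to the respiratory chain, disagreed: its brightest differed by -0.14 ± 0.20, and a dim one, at least 1.93-fold lower, passed only with the 6 arrays taken separately.

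**Figure D3:**
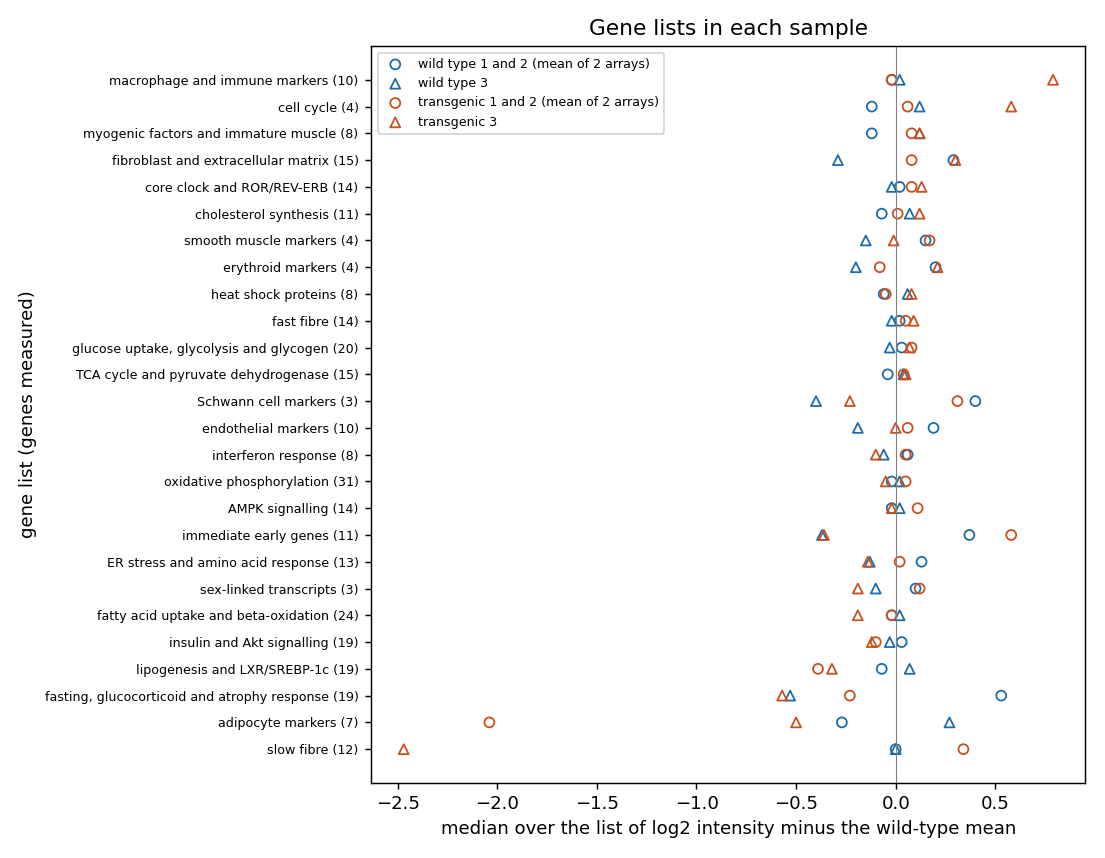
Median over each gene list of log2 intensity minus the wild-type mean, in the 4 samples (arrays 1 and 2 of a group averaged, and replicate 3). The slow-fibre median of transgenic replicate 3 is at -2.47 and that of the other transgenic sample at 0.34.

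The remaining 20 lists had camera adjusted p-values of 0.05 or more and medians between -0.12 and 0.38, with 0 members past the threshold over all probes. Among the signalling and metabolic lists, medians were -0.12 for insulin and Akt signalling, -0.01 for AMPK signalling, 0.07 for glucose uptake, glycolysis and glycogen, 0.01 for oxidative phosphorylation, 0.05 for the TCA cycle and 0.10 for cholesterol synthesis. Insulin and Akt signalling had a camera adjusted p of 0.194 with all samples, and 0.971 with an estimated correlation. Without wild-type replicate 3 its median was -0.12. Akt2 differed by -0.00 ± 0.17, Prkaa2 by -0.09 ± 0.25 and Prkag3 by 0.01 ± 0.23. Prkag2, a regulatory subunit of AMPK, differed by 0.79 ± 0.19 (adjusted p = 0.569), and Pik3r1, a regulatory subunit of PI3-kinase, by -1.14 ± 0.31 (adjusted p = 0.585). Slc2a4, the insulin-responsive glucose transporter, differed by -0.03 ± 0.19, Cav3 by 0.13 ± 0.23 and Ppargc1a by 0.21 ± 0.26. Fgf21 was detected on none of the 6 arrays.

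The core clock list had a median of 0.13. Arntl, which heads the clock's positive arm, differed by -0.08 ± 0.69, Nr1d1 by -0.21 ± 0.27 and Bhlhe40 by 0.86 ± 0.31 (adjusted p = 0.645). Medians were 0.23 for myogenic factors, 0.07 for heat shock proteins, -0.09 for immediate early genes, -0.09 for the ER stress response, 0.03 for the interferon response and 0.38 for the cell cycle. The cell cycle list, with 4 measured genes, had a camera adjusted p of 0.175 with all samples, and 0.971 with an estimated correlation. It was shifted up with the deposited log2 values, without wild-type replicate 1 and without transgenic replicate 2 (adjusted p from 0.00583 to 0.0423). The deposited values may take other probes of these genes. Without wild-type replicate 3 the list's median was 0.69. Of other cell types, medians were 0.19 for fibroblasts and matrix, 0.04 for endothelium, 0.04 for Schwann cells, 0.08 for smooth muscle and 0.07 for erythroid cells. Sex-linked transcripts had a median of -0.11 and a mean of 0.03. The direction of the camera test was opposite to the sign of the median for AMPK signalling, oxidative phosphorylation, cholesterol synthesis, heat shock proteins, the interferon response and erythroid cells, none of which passed.

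The detected probe of Rora was at 12.09 ± 0.08 in wild type and 12.29 ± 0.35 in transgenic samples, a difference of 0.20 ± 0.22 (adjusted p = 0.835). On single arrays it ran from 12.03 to 12.19 in wild type and from 11.95 to 12.54 in the transgenic group. A second Rora probe was detected on none of the arrays. The probes' place in the transcript is not given in the sources used here, so whether either can bind RNA of the truncated human transgene is open, and the values do not check the labels. Acta1, whose human promoter drives the transgene, was at 15.60 ± 0.02 and 15.65 ± 0.06, close to the brightest signal of the array.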

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

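Averaging arrays 1 and 2 changes the count of changed probes: 1 with the samples averaged (0 higher, 1 lower), 54 (20 higher, 34 lower) with 6 separate arrays and 13 (5 and 8) with the RNA sample as a random block. The 6 separate arrays are the design written before the data were examined; the averaging and the random block were chosen after seeing the data. Other counts were 8 (3 higher, 5 lower) both with offset 50 and without background correction, 3 (1 and 2) with median centring and again at adjusted p under 0.10, 7 (2 and 5) with the deposited log2 values, 10 (3 and 7) with an intensity trend, and 0 among probes detected on all 6 arrays, a filter that removes Ucp1. Leaving out single arrays gave 1 to 9 probes changed, 0 to 1 higher and 1 to 8 lower, the most without transgenic replicate 3. A replicate left alone is then assumed to vary like the other group. Leaving out array 1 or 2 kept the other array of the same sample. These fits retained the probes kept with all 6 arrays, since a filter remade without a wild-type array removes Ucp1. Ucp1 passed under all 17 alternatives in which it was tested, with adjusted p from 6.65e-06 to 0.0213 and log2 differences from -7.39 to -5.18. The cause of these differences was not tested. The median of all probes lay between -0.06 and 0.02.

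Replicate numbers showed no clear pairing of the samples: correlations of same-numbered arrays were 4.56e-04, 0.0232 and 0.0616. Of 3 wild-type arrays, 1 correlated best with its own number. Arrays 1 and 2 of a group were nearly alike, so their numbers can hardly be told apart. What remains is the difference between the 2 samples of each group, which correlated at 0.0616 between the groups. Pairing by number is therefore not excluded. With the number as a block the averaged samples again gave 1 probe and 6 lists, and 6 separate arrays gave 15 probes. With 6 separate arrays, leaving out 1 gave 11 to 53 probes, except 418 without wild-type replicate 3. Of the lists, 6 were shifted; leaving out 1 array gave 3 to 7 (3 without transgenic replicate 3), 6 separate arrays gave 3 (lipogenesis, adipocyte and fasting), and camera with an estimated correlation and fry each gave 0. Without transgenic replicate 3 the slow-fibre median turned to 0.34, the macrophage median to -0.02 and Rora to -0.05; leaving out single arrays gave -1.17 to 0.34, -0.02 to 0.46 and -0.05 to 0.24. Across 20 alternatives the lipogenesis, adipocyte and fasting lists each kept their call in 18, slow fibre in 15, fatty acid oxidation in 14 and macrophages in 13. The lipogenesis, adipocyte and fasting lists lost it in the only 2 alternatives without the preset correlation. No alternative left out the sample made of arrays 1 and 2 of a group, so these counts do not test how far a list rests on it. No named gene past the threshold changed sign; 38 of 2356 alternative values did among genes that never passed. Signal over background limits Ucp1 and other genes that were below detection in a group to a bound.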

Other observations

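The tests of explanations here were chosen after their results were seen. Some transcripts stood apart in 1 sample from the other sample of the same group. In transgenic replicate 3, 8 of 12 slow-fibre genes lay over 1 log2 unit below every other sample. Among them Tnnc1 was at 7.71, against 14.15 in transgenic arrays 1 and 2 and 13.43 and 13.07 in wild type, Tnnt1 at 8.20 against 13.30, 12.50 and 12.40, and Myl2 at 10.43 against 14.48, 13.83 and 13.72. Others did not: Pln was at 7.05, the highest of the 4 samples, Casq2 at 7.16 against 7.27 in transgenic arrays 1 and 2, and Csrp3 at 12.83 against 12.51. These genes were named after their values were seen.

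Several clock genes had values in wild-type arrays 1 and 2 apart from those of the other samples. Per2 was at 8.46 in wild-type arrays 1 and 2, against 10.06 in wild-type replicate 3 and 9.88 and 10.04 in the transgenic samples, and Dbp at 9.83 against 11.39, 11.20 and 11.47. Arntl was at 10.36 in wild-type arrays 1 and 2 and at 8.03 in wild-type replicate 3, with 9.24 and 8.99 in the transgenic samples.

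Arrays 1 and 2 of each group were nearly alike. Separate mice that differ as much as replicate 3 does would give a same-gene correlation in the range of the other pairs within a group. Its upper 95% limit was at most 0.113, and the lowest lower limit of those pairs was 0.639. The correlation thus lay below that range. These limits take genes as independent, and the same correlation served to join the arrays, so they are descriptive and no separate test. A candidate explanation is 1 RNA sample or pool on both arrays, for which the larger correlation was 0.0279. The labels do not say which arrays share RNA, and separate mice pooled before labelling stay open.

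Ucp1 and Cidea, transcripts of brown fat, and several lipogenic transcripts had lower means in the transgenic samples. Of these, Ucp1 alone passed the threshold over all probes. Less adipose tissue of every kind, in equal share, would lower bright fat-cell markers that muscle fibres lack as far as Ucp1 and Cidea. Of such markers, Adipoq was at -2.04 and -0.22 and Cidec at -2.42 and -0.50 from the wild-type mean in the 2 transgenic samples. Cidea was at -4.01 and -4.07 and Ucp1 at -7.22 and -7.45. Ucp1 and Cidea thus fell further in both samples. They were picked as the largest falls, however, so the gap is partly set by that choice and does not exclude this explanation. For the lipogenic genes less adipose tissue stays open too. The median of 5 markers of any depot, 2 of which muscle fibres also express, was -1.17 in transgenic arrays 1 and 2 and -0.45 in transgenic replicate 3. Brown adipocytes in the wild-type samples may be the source of Ucp1. Of 6 other measured brown markers, 1 also expressed by muscle, all had lower transgenic means and 4 were lower in both transgenic samples. Their median was -0.78, with Slc27a2 at -2.87, Slc36a2 at -1.43, Ebf2 at -0.29 and Zic1 at -0.14. In the transgenic samples Slc27a2 stood at 5.15 and 5.07 and Slc36a2 at 5.02 and 5.46, near the undetected level of Ucp1 (5.12). Background limits the fall of such dim genes, so the median does not decide it. An effect of the transgene, in the fibres or through fat cells, stays open and untested.

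The fasting, glucocorticoid and atrophy list was lower in the transgenic samples. Its median in wild-type replicate 3 was -0.12 from the transgenic mean, and in wild-type arrays 1 and 2 it was 1.05 above it. A state of 1 wild-type sample that the other does not share, such as a longer fast or another hour of sampling, may therefore account for the shift. An effect of genotype stays open with 2 samples per group.

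With the 6 arrays taken as separate samples, 10 splits into 3 and 3 are too few for a share under 0.05. The real split called 54 probes, the only 1 of 10 to call as many, and the highest other called 3. These splits treat the 6 arrays as exchangeable and ignore that arrays 1 and 2 of a group were counted as 1 sample. Of the 9 other splits, 8 part such arrays and called 0 probes, and the 1 that keeps them together called 3. For gene lists the real split shifted 3 and the highest other 7, and 9 of 10 splits shifted as many as the real one.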
